A study of Mus musculus with 8 samples.

How the data were processed

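Methylation of adenosine in messenger RNA at the N6 position (m6A) was profiled by m6A-seq, in which RNA fragments are captured with an antibody against m6A and sequenced beside uncaptured input RNA. The labels list 8 libraries of primary airway epithelial cells from the lungs of wild-type mice, which fell into 4 groups of 2 libraries each: immunoprecipitated (IP) and input RNA of mice labelled HDM, and IP and input RNA of mice labelled PBS. Per the labels' protocols, the cells were sorted with antibodies against CD326, the epithelial adhesion molecule EpCAM, and CD45, a surface protein of leukocytes, and the m6A libraries were built with a stranded mRNA kit. The gates, the dose and timing of HDM and whether the replicates came from separate animals are not given in the sources used here.

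The values used were the authors' own comparison of HDM with PBS, in a pair of deposited tables that list only called sites, those with a higher and those with a lower level in HDM. Reads were trimmed with cutadapt and the genome build was mm10, per the submitters' processing notes. Sites carried diffReps identifiers, per the file headers and their entries; diffReps slides windows along the genome and tests them between conditions. The aligner, the test behind each p, the normalization and the way IP was set against input are not given in the sources used here. Each site had a fold, which is a linear ratio of HDM to PBS for higher sites and of PBS to HDM for lower sites, per the file headers and the column of directions in the deposited tables. Each site also had the authors' p-value and the authors' false discovery rate (FDR). The score in the deposited tables equalled the −log10 of the authors' p-value at 4424 of 4424 sites, within 1e-9. The smallest fold was 2 and the largest p-value 0.0500, while the largest FDR was 0.309, so the deposited calls followed the p-value and not the FDR. No value per library was in these tables. The depth of each library is therefore unknown, no replicate spread, no test across the libraries and no check of the replicates against each other was possible, and the input libraries and the expression values named in the labels were not analysed here.

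Many large folds were whole multiples of 0.1. Of the 704 higher sites with a fold of at least 20, 670 had a fold that was a whole multiple of 0.1 within 1e-06, against 23 of the 2353 higher sites with a smaller fold. Among lower sites these numbers were 532 of 535 and 17 of 832. Each such fold of at least 20 went with a single p-value in its direction (87 of 87 distinct folds among higher sites, 66 of 66 among lower sites). A fold that occurs at only 1 site meets this by construction, and such folds were not counted apart. Such values arise when a mean is divided by a floor of 1 because the other condition had no or almost no signal. This reading was inferred from the values and is not stated in the sources used here. The term floor fold is used below for them, and their size is neither a measured ratio nor a bound. The commonest were 22.7 at 149 higher sites (authors' p 0.0275, FDR 0.240) and 24.3 at 107 lower sites (authors' p 0.0322, FDR 0.241), so neither has an FDR under 0.05 where printed below.

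Coordinates are given as the deposited tables give them, on build mm10. Starts lay on a 20 bp grid at 53.7% of sites and ends at 55.3%, while other ends were off it; 257 sites started 1 bp before the first base of the named gene, so that such starts appear to count from 0. Gene identifiers were given for 4320 sites and 4291 of these were found in a RefSeq gene table of assembly GRCm38.p6, which has the same coordinates as mm10. Of these, 4010 sites (93.5%) lay inside the span of the named gene. Of all sites, 551 overlapped the span of another gene, wholly or in part, and such sites are said below to lie in or inside it. Without strand these cannot be assigned to 1 gene with certainty. Of the sites whose values are printed, such an overlap held for ones in Cry2, Csf1, Csf1r, Cxcl10, Fcgbp, Fyb, Lss, Myh6, Rora, Ubap2l, Chd1, Dhx58, Nhp2 and Sertad1. Printed sites of Csf1r, Cxcl1, Hmox1, Lyz2, Nr1d2, Actg2, Asns, Cyp2f2, Ern1, Scgb1a1, Sertad1 and Wtap reached beyond or lay outside the span of the named gene. Exons, coding sequence and strand were not used here, and the planned analyses of transcript regions, of the DRACH sequence motif and of each site across libraries were not run.

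Sites were counted per direction, with a Wilson 95% interval for the share of higher sites that covers counting of sites only. Before the data were examined, 23 gene lists with 835 genes were fixed for pathways and cell types of the lung, together with the tests, the alternatives named as such in the closing section and the rule for named genes. For each list, genes with only higher sites and genes with only lower sites were counted among its members and among all other genes with a site, and compared with a two-sided Fisher's exact test; the 211 genes with sites of both directions were left out. P-values were adjusted by the Benjamini-Hochberg method over the lists with at least 5 such genes, and adjusted values under 0.05 counted as passing. Shares of a list carry exact Clopper-Pearson 95% intervals. Genes are the units of these tests, so a p-value compares lists within this 1 comparison and says nothing on the spread between mice.

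The rule for named genes took Clock and Ythdf1 in any case and every gene of the m6A machinery and circadian clock lists with a called site. In each direction it also took the 10 largest folds and the 5 smallest p-values among genes with approved symbols and up to 5 genes with the most sites. From each other list it took up to 4 genes with the largest absolute log2 fold. It gave 124 genes with 181 sites, of which 97 had a floor fold and 25 also lay in another gene. The values of some of these genes are not reported here. Other genes named beside them were chosen after their values were seen.

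Alternatives fixed beforehand were a fold of at least 4, a p-value of at most 0.0005, merging of sites within 200 bp, genes in place of sites or sites in place of genes, and the direction of the most significant site for genes with both. Added after the data were seen were an FDR under 0.05, floor folds left out, sites under 50 bp left out, sites inside another gene's span left out, a second list of macrophage genes, a second list of stromal genes, tests of the annotation terms in the deposited tables, the sets of Hox and heat shock genes and the comparison of sites within a gene. Each second list was fixed before its genes were looked up. One annotation entry that was masked in the tables was left out. The list test was tested on simulated directions for the 3544 genes with a site. With no list shifted, at least 1 list passed in 1% of 100 simulations. A mesenchymal list set to 15% higher passed in 90%, an NF-kB list set to 98% higher in 62%, and a circadian clock list set to 98% higher in 0%, because that list is too small. Each simulated gene had a single direction at all of its sites, so genes with both directions, which the real test leaves out, were counted. Directions were also drawn independently for each gene. These pass rates therefore hold for an easier setting than the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.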

Results

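The m6A landscape of airway epithelial cells was compared between mice treated with HDM, the usual abbreviation of house dust mite in work on allergic airways, and mice given PBS. The series is about the m6A reader YTHDF1 and the circadian transcription factor CLOCK in allergic airway inflammation, and the comparison asks which transcripts carried more or less m6A signal after HDM. Each condition had 2 IP and 2 input libraries, and 4424 sites in 3544 genes were called between the conditions by the authors. No replicate values accompanied the sites, so every fold, p and FDR of a single site given here is the authors' and comes without an error; the depth behind it is unknown. Sites were 1 to 1679 bp long, with a median of 178 bp.

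Among sites that were higher in HDM, those of C3ar1, Tlr8 and Selplg had the largest listed folds. These were floor folds, so their order is not one of measured size. In the authors' deposited table the complement receptor gene C3ar1 had the largest, a floor fold of 487.5 (FDR 6.25e-06), at a site on chromosome 6 from 122850201 to 122851264 inside the gene. The authors' deposited table gave floor folds of 305.8 for the endosomal RNA sensor Tlr8, 243.5 for the selectin ligand Selplg, 198.6 for the NADPH oxidase subunit Cybb, 180.5 for the integrin Itgam, 180.3 for the interleukin 10 receptor Il10ra and 172.9 for the T cell and myeloid adaptor Fyb. Also among these were Trim34b at 186.1 and the homeodomain genes Dlx1 at 182.5 and Pou3f2 at 178.8, all floor folds in the authors' deposited table. The smallest p of a higher site in the authors' deposited table was that of Ppp1r18, an actin-associated phosphatase subunit, with a fold of 4.22 (p 9.16e-11), which was not a floor fold.

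Lower sites had other leading genes. Tango6 had the largest fold of a lower site in the authors' deposited table, a floor fold of 101.3 (FDR 0.00208), on chromosome 8 from 106850201 to 106850440. The authors' deposited table gave floor folds of 85.9 for the transcription factor Tfcp2, 84.8 for Ppp2r3d, 77.8 for the elastin gene Eln, 76.2 for Sertad1, 74.5 for Tmem201, 74.3 for the tRNA methyltransferase Mettl1, 67.7 for Zer1 and 64.7 for Il11ra2. The smallest p-values of lower sites in the authors' deposited table were 4.29e-13 for Plac9a with a fold of 7.39, 3.42e-12 for the RNA polymerase subunit Polr1d with a fold of 6.19 and 9.48e-10 for the ribonucleoprotein gene Nhp2 with a fold of 4.47. After these came Rbm6 with a fold of 36.6 and Gdpgp1 with a fold of 8.15 in the authors' deposited table. Tmem201 and Gdpgp1 also had a higher site each, with folds of 2.37 and 2.31 in the authors' deposited table. Plac9a, Il11ra2 and Trim34b have near-identical paralogs, so reads at their sites cannot be assigned with certainty.

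Over all sites, 3057 were higher and 1367 lower in HDM, a share of 69.1% higher (Wilson 95% interval 67.7 to 70.4). The share depended on the threshold and was 64.6% at a fold of at least 4, 85.0% at an FDR under 0.05 (1268 higher and 224 lower sites) and 87.2% at a p of at most 0.0005. Floor folds made up 21.9% of higher sites (20.5 to 23.4) and 38.9% of lower sites (36.4 to 41.5), a difference with a Fisher's exact p of 9.54e-31. That test counts sites, which are not independent within a gene, so its p is too small. With them the median fold was 4.07 for higher and 6.61 for lower sites. Without them it was 3.38 (interquartile range 2.55 to 5.20) for higher sites and 3.34 (2.45 to 5.43) for lower sites.

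**Figure D1:**
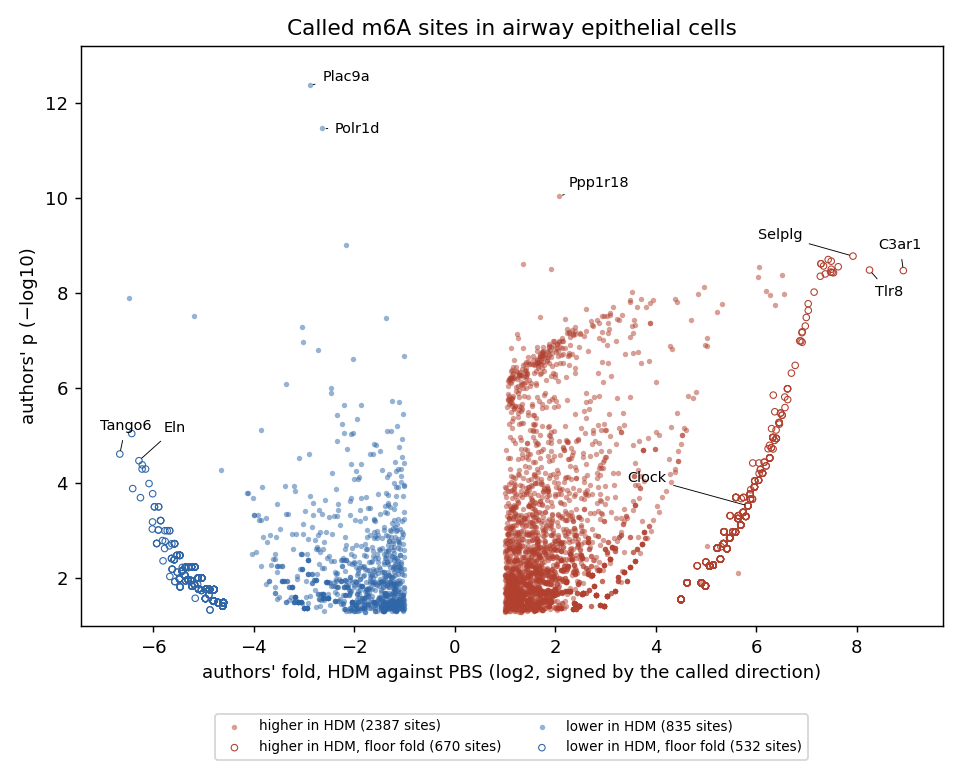
Each point is 1 called site, placed by the authors' fold on a log2 axis (positive for higher and negative for lower in HDM) and the −log10 of the authors' p. Open circles are the 670 higher and 532 lower sites with a floor fold, which lie along a narrow band in each direction, with Clock among them.

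Core clock and clock-associated genes carried mostly higher sites. Of the 9 genes of the circadian clock list with a site, 7 had only higher sites, none had only lower sites, and Per2 and Cry2 had sites of both directions. The gene at the centre of the series, Clock, had a single called site, higher in HDM with a floor fold of 57.2 in the authors' deposited table (p 0.000296, FDR 0.0138). That site spanned 33 bp of chromosome 5, from 76304367 to 76304400, inside the Clock gene and 1203 bp from the end of its span with the higher coordinate. Because the fold was a floor fold, 9 higher sites shared the fold and p of the Clock site in the authors' deposited table, and 768 higher sites had a p at or below it; 6.35% of higher sites were shorter.

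Several clock genes had sites with a low FDR and no floor fold. Nr1d1, which encodes the clock repressor REV-ERB alpha, had sites with folds of 5.29 (FDR 2.39e-05) and 4.15 (FDR 0.000349) in the authors' deposited table, the first on chromosome 11 from 98770187 to 98770400. Its relative Nr1d2 had a fold of 4.04 (FDR 0.00489) and the nuclear receptor gene Rora had folds of 4.77 and 4.11 at 2 of its 3 sites in the authors' deposited table. For Per3 the authors' deposited table listed a floor fold of 57.2 (FDR 0.0138) and a fold of 2.72 (FDR 0.246), and for Sirt1 a fold of 2.97 (FDR 0.0829). The opposed sites of Per2 had folds of 2.88 higher (FDR 0.272) and 2.76 lower (FDR 0.298) in the authors' deposited table. Cry2 had a higher fold of 3.96 (FDR 0.0412), at a site that also lay in the span of D930015M05Rik, and a lower floor fold of 24.3 (FDR 0.241) in the authors' deposited table. As a list, the circadian clock genes did not pass (100% higher, exact 95% interval 59.0 to 100, against 68.7% of other genes; Fisher's exact adjusted p 0.320). With 7 genes, 0.107 was the unadjusted p with every gene higher, so a higher shift of this list could not have passed.

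Among genes of the m6A machinery, Ythdf1 had no called site in either direction. Its paralog Ythdf2, a cytoplasmic reader that promotes decay of m6A-marked mRNA, had a higher site with a fold of 5.14 (FDR 0.0239) in the authors' deposited table, on chromosome 4 from 132212041 to 132212240. Other readers with higher sites in the authors' deposited table were Igf2bp2 with a fold of 4.16 (FDR 0.000133), the nuclear reader Ythdc1 with 3.09 (FDR 9.68e-05) and Hnrnpa2b1 with 2.21 (FDR 0.241). The authors' deposited table placed the writer complex genes in opposite directions, Rbm15 higher with a fold of 2.01 (FDR 0.00875) and Wtap lower with a fold of 3.60 (FDR 0.169). Fmr1 had a higher site with a fold of 2.12 (FDR 0.0768) and a lower site with a fold of 7.54 (FDR 0.0801) in the authors' deposited table. In this list 5 genes had only higher and 1 only lower sites, which did not pass (83.3% against 68.7% of other genes higher, Fisher's exact adjusted p 0.757). With 6 genes, 0.186 was the smallest unadjusted p that an all-higher list could give.

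**Figure D2:**
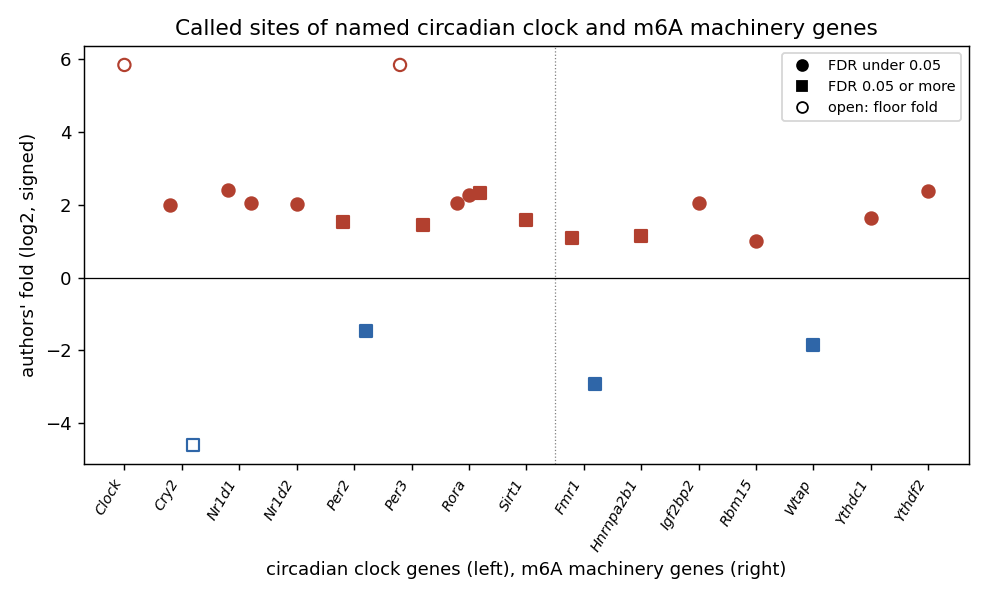
Each symbol is 1 called site of a circadian clock gene (left) or m6A machinery gene (right) named in the text, with the authors' fold on a log2 axis, positive for sites higher in HDM. Circles have an FDR under 0.05, squares do not, and open symbols are floor folds; the sites of Clock and Per3 at the top share a floor fold of 57.2 in the authors' deposited table.

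Structural and fibroblast genes went the other way from most genes with a site. Of the 13 genes of the mesenchymal list with a site, 10 had only lower sites, none had only higher sites, and Pdgfra, Cspg4 and Twist1 had both. Eln had 3 lower sites, with a floor fold of 77.8 (FDR 0.00269) and folds of 5.25 and 3.21 in the authors' deposited table, the first on chromosome 5 from 134702595 to 134702700. The authors' deposited table listed the intermediate filament gene Vim with a lower fold of 2.31 (FDR 0.00617), the collagen genes Col6a1 with 2.34, Col6a3 with 2.76 and Col3a1 with 2.14, and Col6a2 with a floor fold of 36.0. Desmin (Des) had a fold of 3.80, Thy1 a fold of 2.36 and the mesothelial gene Upk3b a fold of 8.36, all lower in the authors' deposited table. This list passed (0% higher, exact 95% interval 0 to 30.8, against 69.0% of other genes; Fisher's exact adjusted p 0.000154), and it was the 1 of 18 tested lists that did. Only Eln and Vim had a site with an FDR under 0.05, so the list could not be tested at that threshold, and at a fold of at least 4 it no longer passed (adjusted p 0.107). A second list of stromal genes, added after the data were seen, had 4 genes higher and 17 lower.

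Leukocyte genes carried higher sites in cells that had been sorted with an antibody against CD45. Of the 10 leukocyte-list genes with a site, 9 had only higher sites, none had only lower sites and Itgam had both. The macrophage scavenger receptor gene Marco had 6 higher sites with floor folds up to 166.1 in the authors' deposited table, and the Fc receptor subunit gene Fcer1g had a floor fold of 118.7. For Tyrobp, an adaptor of myeloid receptors, the authors' deposited table gave a fold of 19.5 (FDR 4.09e-05), and for the macrophage colony-stimulating factor receptor Csf1r a fold of 12.5 (FDR 1.37e-05) at a site that ran past the end of Csf1r into the span of Hmgxb3. The granulocyte receptor Csf3r had a floor fold of 89.7, and Lyz2, an alveolar-list gene that macrophages also express, had 5 higher sites, 1 of them with a fold of 37.2 (FDR 1.57e-05), in the authors' deposited table. By genes, the leukocyte list did not pass (100% higher, exact 95% interval 66.4 to 100, Fisher's exact adjusted p 0.290), and 0.0649 was the smallest unadjusted p that 9 genes could give in the higher direction. Counted by sites, 96.2% of its 26 sites were higher (adjusted p 0.0112), but these came from 10 genes, so the sites are not independent and that p is too small. A second list of macrophage genes, added after the data were seen, had 34 genes higher and 2 lower (adjusted p 0.000387), and 18 higher and 2 lower without floor folds (90.0% against 73.5% of other genes, p 0.126).

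The club cell secretoglobins Scgb3a1 and Scgb1a1 had lower sites with folds of 4.24 (FDR 0.136) and 3.94 (FDR 0.147) in the authors' deposited table, and Dapl1 and Cyp2f2 lower sites with folds of 7.66 and 2.30. Notch3 was the 1 higher gene of the club and basal cell list, with a fold of 3.22 in the authors' deposited table, beside 4 lower genes (adjusted p 0.258). The alveolar list had 3 higher and 4 lower genes (adjusted p 0.483); the lung lineage factor Nkx2-1 had a higher fold of 6.26 (FDR 0.00925) and the fatty acid synthase gene Fasn a lower fold of 3.43 (FDR 0.0211) in the authors' deposited table. In the endothelial list 2 genes were higher and 3 lower (adjusted p 0.462). Among them were Kdr and Vwf with lower floor folds of 24.3 (FDR 0.241 each) and Ephb4 with a higher one of 39.1 (FDR 0.0779) in the authors' deposited table. Muc1 was the 1 goblet-list gene with a site, lower with a fold of 2.08 (FDR 0.0337) in the authors' deposited table. Of the ciliated-cell genes, Rsph4a was higher and Dnah9 lower with floor folds of 44.5 and 30.9 in the authors' deposited table, and Tppp3 had both directions. The goblet and ciliated lists held too few genes to test.

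**Figure D3:**
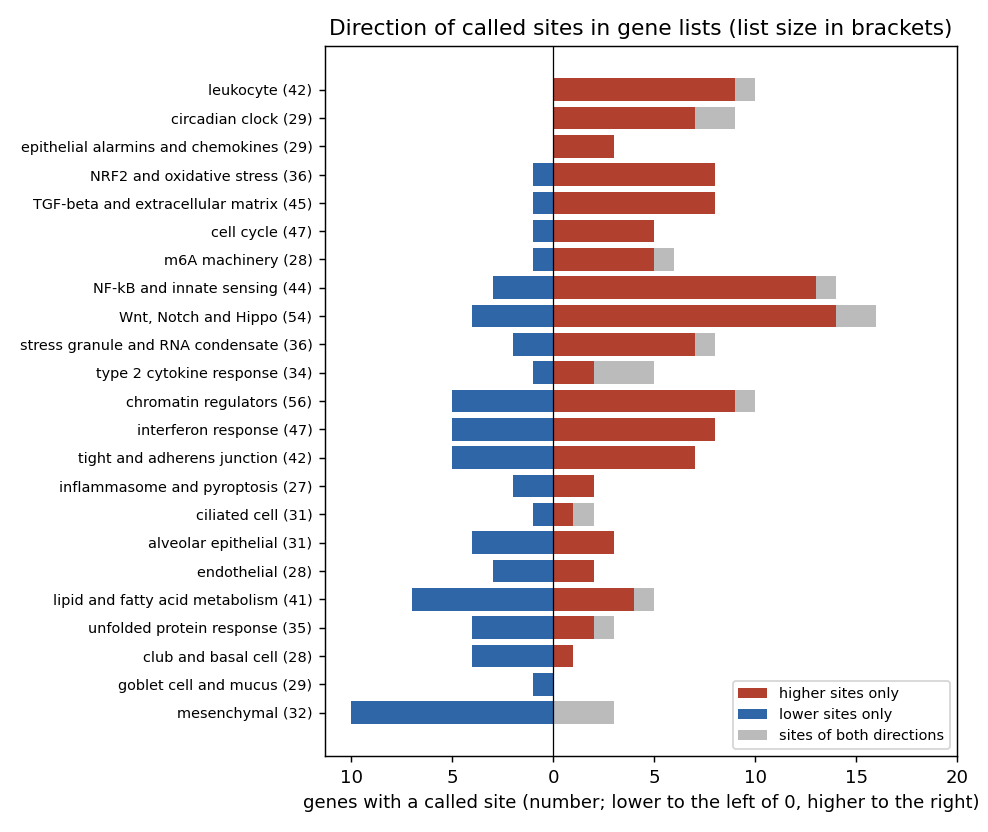
Bars count the genes of each list that had only higher sites (right of 0), only lower sites (left of 0) or both (grey, added on the right), with the number of genes fixed for the list in brackets. The mesenchymal list, with 10 genes lower and 0 higher, was the 1 list that passed the exact test.

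Genes of the NF-kB and innate sensing list went both ways. Of the 17 with a site, 13 had only higher and 3 only lower sites, and Nod2 had both; the list did not pass (81.3% against 68.7% of other genes higher, Fisher's exact adjusted p 0.684). The inhibitor genes Nfkbia and Nfkbie had folds of 8.33 (FDR 2.15e-05) and 8.13 (FDR 4.09e-05) in the authors' deposited table, and Tnfaip3, another brake on the pathway, had a fold of 2.19 (FDR 0.000116). The authors' deposited table gave higher floor folds of 51.8 for Nod2 (FDR 0.0266), 44.5 for the kinase Chuk (FDR 0.0372) and 33.7 for Tlr1 (FDR 0.0904). It gave lower floor folds of 42.6 for Nod1 (FDR 0.104) and 24.3 for a second Nod2 site (FDR 0.241). At an FDR under 0.05 the list had 7 genes higher and 0 lower. With 83.7% of other genes higher at that threshold, it did not pass (Fisher's exact adjusted p 0.779). Among epithelial alarmins and chemokines, 3 genes were higher and none lower, which was too few to test: Cxcl1 with a fold of 12.6 (FDR 0.00666), Csf1 with 3.72 (FDR 0.00462) and Cxcl10 with 3.24 (FDR 0.183) in the authors' deposited table.

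Interferon-response genes went both ways, with 8 higher and 5 lower (adjusted p 0.757). The transcription factors Irf1 and Irf8 had higher folds of 22.6 (FDR 0.00142) and 16.1 (FDR 0.000142) in the authors' deposited table. Rtp4, Dhx58 and Oas2 had lower floor folds of 37.7 (FDR 0.0935), 29.4 (FDR 0.183) and 27.8 (FDR 0.241) in the authors' deposited table. At an FDR under 0.05 this list had 4 genes higher and 0 lower, too few to test, while 83.8% of other genes were higher. Type 2 cytokine genes had 2 higher, 1 lower and 3 genes with both directions, and were not tested. The signalling inhibitor Socs1 was among the last, with floor folds of 89.7 higher (FDR 0.000446) and 47.8 lower (FDR 0.0795), as was Fcgbp, with a higher fold of 5.44 and a lower floor fold of 41.0 in the authors' deposited table. Alox12e and the receptor subunit Il2rg had higher floor folds of 49.8 (FDR 0.0216) and 30.1 (FDR 0.152) in the authors' deposited table. In the inflammasome list, also not tested, the authors' deposited table listed Aim2 and Il1b as higher, with floor folds of 44.5 (FDR 0.0372) and 31.8 (FDR 0.169). Casp8 and Ninj1 were lower there, with a fold of 2.32 (FDR 0.162) and a floor fold of 49.2 (FDR 0.101).

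The NRF2 and oxidative stress list had 8 genes higher and 1 lower and did not pass (88.9% against 68.7% of other genes higher, Fisher's exact adjusted p 0.520). Gclc, the catalytic subunit of glutathione synthesis, had a fold of 11.2 (FDR 1.21e-05), the NRF2 competitor Bach1 a fold of 7.86 (FDR 1.81e-05) and the heme oxygenase gene Hmox1 a fold of 5.30 (FDR 5.85e-05) in the authors' deposited table. Maf had a fold of 12.6 and Duox1 a floor fold of 49.8, and the peroxiredoxin gene Prdx6 was lower with a fold of 3.21, in the authors' deposited table. TGF-beta and matrix genes were also 8 higher and 1 lower (adjusted p 0.520), with the repressors Zeb1 at 11.3 (FDR 0.000245) and Zeb2 at 3.80 (FDR 6.12e-06), Ltbp3 at 7.02 and Mmp12 at a floor fold of 22.7 in the authors' deposited table. The lower gene was the laminin gene Lamb2 (FDR 5.66e-05) in the authors' deposited table. The other higher genes were Smad2, Smurf1, Smurf2 and Snai2, so few structural matrix genes stand behind the higher share of this list. The proteinaceous extracellular matrix term described below went the other way, with 19 genes higher and 37 lower.

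Lipid and fatty acid metabolism genes went both ways. By genes, 4 were higher and 7 lower (36.4% against 68.9% of other genes, Fisher's exact adjusted p 0.258), and by sites 9 were higher and 8 lower. At an FDR under 0.05 there were 4 higher genes and 1 lower gene. The nuclear receptor gene Ppard had a higher fold of 5.49 (FDR 0.00120) and its coactivator gene Ppargc1a had 4 higher sites, with folds of 2.99 to 5.06, in the authors' deposited table. The list also held Abcg1 and Nr1h2 at lower floor folds of 35.8 and 26.1 and Lss at a higher one of 22.7 in the authors' deposited table; Dhcr7 had both directions, with a higher floor fold of 44.5. The unfolded protein response list had 2 genes higher and 4 lower and did not pass (Fisher's exact adjusted p 0.290). Its members in the authors' deposited table included Asns with a lower fold of 11.9 (FDR 0.0777) and Pdia3 with a lower fold of 5.05 (FDR 0.115). The stress sensor Ern1 had a lower floor fold of 26.1 (FDR 0.241) in the authors' deposited table. Sdf2l1 had a lower floor fold of 32.7 (FDR 0.136) beside a higher fold of 3.72 (FDR 0.241) there. At an FDR under 0.05 the list had 1 gene higher, Ddit3, at a site that also lay in the span of Mars1, and 1 lower, Atf4.

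Junction genes were 7 higher and 5 lower (adjusted p 0.757). The tight junction gene Ocln had a higher floor fold of 82.6 (FDR 0.00122) in the authors' deposited table. Lower floor folds there were 41.0 for Cldn7 and for Inadl, now named Patj, and 39.3 for Marveld3 (FDR 0.0935 each). At an FDR under 0.05 the junction list had 4 genes higher and 0 lower, too few to test, while 83.8% of other genes were higher. Wnt, Notch and Hippo genes were 14 higher and 4 lower (adjusted p 0.757); Rbpj, the transcription factor of Notch signalling, had a higher fold of 4.83 (FDR 2.83e-05) in the authors' deposited table. In the same list the authors' deposited table gave a higher floor fold of 37.4 for Notch4 and lower floor folds of 47.6 for Lef1, 29.4 for Wwtr1 and 24.3 for Wnt7b, of which Lef1 and Wnt7b also had higher sites. Chromatin regulators were 9 higher and 5 lower (adjusted p 0.774), with Whsc1l1, now named Nsd3, at a higher fold of 7.72 (FDR 0.00281), Hdac4 at a higher fold of 3.72, Chd1 at a lower floor fold of 27.8 and Dnmt3a at 7.17 lower and 4.98 higher in the authors' deposited table. Stress granule and RNA condensate genes were 7 higher and 2 lower (adjusted p 0.772), with Ubap2l at 13.7 (FDR 0.0372) and Caprin1 at 6.69 higher and Taf15 at 8.36 lower in the authors' deposited table. Cell cycle genes were 5 higher and 1 lower (adjusted p 0.757). The authors' deposited table gave Myc a higher fold of 4.03 (FDR 0.198), E2f3 one of 5.16 (FDR 0.102) and Cenpe a floor fold of 22.7 (FDR 0.240). E2f8 had a lower fold of 3.60 (FDR 0.169) there. At an FDR under 0.05 the cell cycle list had 2 genes higher and 0 lower, too few to test, while 83.8% of other genes were higher.

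Some genes collected many sites. The giant sarcomere gene Ttn had 9 higher and 5 lower sites, and the cardiac myosin gene Myh6 had 9 sites, each higher with a fold between 2.02 and 4.29 in the authors' deposited table. Fyb had 8 higher sites and the leukocyte gene Cyth4 had 6. Lower sites clustered in Rp1 and the collagen gene Col11a1 with 4 each, and in the stromal marker Cd248 with 3, whose folds in the authors' deposited table ran from 2.69 to 3.29. Fewer of these sites had an FDR under 0.05: 3 in Ttn, 2 in Myh6, 6 in Fyb, 4 in Cyth4, 1 in Rp1, 0 in Col11a1 and 2 in Cd248. In all, 650 genes had at least 2 sites, and 211 of them (32.5%) had sites of both directions.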

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

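An FDR under 0.05, the removal of floor folds, short sites or sites in another gene's span were chosen only after the data were seen; the others were fixed before. Higher sites outnumbered lower ones under each alternative. A fold of at least 4 left 1555 higher and 853 lower sites (64.6% higher), a p of at most 0.0005 left 858 and 126 (87.2%), an FDR under 0.05 left 1268 and 224 (85.0%), and without floor folds 2387 and 835 remained (74.1%). The drop in counts follows from the construction of these thresholds, whereas the cause of the shift in share was not tested. Merging, counting genes and leaving out sites under 50 bp gave shares of 68.8% to 69.3%.

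The number of lists that passed was 0 at a fold of at least 4, 0 at a p of at most 0.0005, 0 at an FDR under 0.05, 2 with sites in place of genes, and otherwise 1. At a fold of at least 4 the mesenchymal list was 14.3% higher (adjusted p 0.107), with fewer genes left, and under the p and FDR thresholds it had under 5 genes and no value. It passed with sites in place of genes, by the most significant site, and without floor folds, short sites or sites in another gene (adjusted p 1.63e-05 to 0.000723). Of 103 alternatives for the other lists, 94 kept direction and side of the threshold; the leukocyte list had an adjusted p of 0.0112 by sites. Counting sites treats the several sites of a gene as independent, which makes p-values by sites too small, so neither list pass by sites adds to the test by genes. Against the other genes, 8 reversed, none with an adjusted p under 0.05, and the cause was not tested: interferon (66.7% higher at a fold of at least 4, 77.8% without floor folds), TGF-beta (83.3% at an FDR under 0.05), Wnt, Notch and Hippo (60% at a fold of at least 4, 83.3% at an FDR under 0.05), stress granule (60% at a fold of at least 4) and chromatin regulators (100% at a p of at most 0.0005 and at an FDR under 0.05).

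No paired analysis was possible because the deposited tables hold no value per library. For the same reason leaving out replicates, other normalizations, pseudocounts and low-value filters were not run, nor were recomputed folds. Alternatives for transcript regions and sequence motifs were not run either. With depth unknown, a site with a floor fold cannot be told from one sampled too thinly in the other condition.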

Other observations

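The annotation terms, the Hox and heat shock sets, the second gene lists, the comparison of sites within genes and the test of lower epithelial purity were chosen only after the data were seen. Genes annotated with sequence-specific DNA binding, which are not all transcription factors, carried higher sites more often than other genes. Of 127 genes annotated in the authors' deposited table with sequence-specific DNA binding, 110 were higher and 17 lower (86.6% against 67.6% of other genes, Fisher's exact adjusted p 0.000332 over 643 terms). Among the higher ones were Jun with folds of 3.43, 3.38 and 2.09, Atf3 with a fold of 3.38 and Ets1 with a fold of 3.21, and among the lower ones Fosb with a floor fold of 24.3 and a fold of 5.23, all in the authors' deposited table. The 8 Hox genes with a site were all higher (Fisher's exact p 0.0637, the smallest that 8 higher genes can give, and 0.107 adjusted over the Hox and heat shock sets), among them Hoxc6 with a floor fold of 128 and Hoxb9 with a fold of 5.38 in the authors' deposited table. The Hox set was chosen after the data were seen and its genes belong to the sequence-specific DNA-binding term, so their shared direction adds no evidence. At an FDR under 0.05 the sequence-specific DNA-binding term was 93.3% higher against 83.2% of other genes and no longer passed (adjusted p 0.576). Over all sites, the broader DNA binding term did not pass (74.5% against 67.5% of other genes, Fisher's exact adjusted p 0.197). The nucleus term did, with 842 genes higher and 290 lower (Fisher's exact adjusted p 1.78e-05), so a higher share was not particular to DNA-binding genes. At an FDR under 0.05 the nucleus term did not pass (Fisher's exact adjusted p 0.436). The term for transcription factor activity was 79.9% higher against 67.6% of other genes (Fisher's exact adjusted p 0.0301). It too no longer passed at an FDR under 0.05 (Fisher's exact adjusted p 0.641).

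Extracellular matrix genes went the other way. The proteinaceous extracellular matrix term had 19 genes higher and 37 lower (33.9% against 68.9%, Fisher's exact adjusted p 3.79e-05) and was the 1 of the 10 passing terms that also passed at an FDR under 0.05 (adjusted p 0.0433). Its lower genes in the authors' deposited table included the Wnt antagonist Sfrp1 with a fold of 17.3 (FDR 0.00868), Cthrc1 with 7.17 (FDR 0.0287) and Thbs2 with 3.65 (FDR 0.0101), and its higher genes Tgfbi with 7.51 (FDR 0.00182). Without the genes of the leukocyte, mesenchymal and second lists it had 17 genes higher and 22 lower (43.6% against 68.8%) and an adjusted p of 0.0904. Acute phase and heat shock genes were picked after their folds were seen, so a test of their shared direction carries no evidence. The authors' deposited table gave folds of 93.8 and 82.9 for the serum amyloid gene Saa3, 11.8 for Dnajb1 and 8.44 for Hsp90aa1; Hspa1a, Hspa1b and Hspa1l were also higher, but the first pair are near-identical and all lie side by side, so their reads cannot be assigned with certainty.

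Leukocyte-list genes carried higher sites (9 of 9 with a single direction), and a candidate explanation is RNA of macrophages in the HDM samples: in a second list of 101 macrophage genes sharing no gene with the first, 94.4% of the 36 genes with a site were higher against 68.5% of other genes (Fisher's exact adjusted p 0.000387), among them C1qa with a fold of 7.49, Apoe with 9.38, Itgb2 with 19.7 and Cd84 with a floor fold of 82.8 in the authors' deposited table. The share was 90.0% against 73.5% (p 0.126) once floor folds were left out and 100% against 83.5% at an FDR under 0.05 (p 0.0367), Plet1 and Apoe of that list are not restricted to macrophages, and a CD45 gate that excluded leukocytes would remove such cells. Site pairs over 1 kb apart in leukocyte and macrophage genes went the same way in 92.5% of 53 pairs, but a mean of 90.4% arises when directions are permuted among the sites of these lists (p 0.444), so whether the signal follows transcript amount could not be decided. A loss of epithelial purity that raises every other cell type alike was predicted to raise the share of higher genes in the mesenchymal list too. That list had a share of 0% higher (Fisher's exact adjusted p 0.000154), against the prediction. The prediction assumes that site signal follows transcript amount, which could not be decided, so the list cannot decide on this explanation. Its share was also already known when the explanation was written down, so it is no new test. A methylation change in leukocytes or in epithelial cells that express these genes after HDM stays open, untested without values of the input libraries.

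Mesenchymal-list genes carried lower sites. Fewer stromal cells in the HDM samples may account for it: in a second list of 85 stromal genes, 19.0% of the 21 genes with a single direction were higher against 69.1% of other genes (Fisher's exact adjusted p 7.07e-06), and the share was 18.8% without floor folds and 30.0% at an FDR under 0.05. Lower genes included Igfbp5 with a fold of 9.95, Emilin2 with 11.1 and Actg2 with 6.83, and Vim of the first list is also expressed by leukocytes, whereas Tpm1 and Cald1 were higher with folds of 2.23 and 5.50 in the authors' deposited table. Whether the signal follows transcript amount could not be decided, since 69.2% of 13 site pairs over 1 kb apart went the same way against a mean of 68.7% with directions permuted among the sites of these lists (p 0.601). A CD326 gate that kept epithelial cells would remove stromal cells, and lower methylation of these transcripts under HDM stays open as well.

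Sites of a gene tended to share a direction. Of 1056 pairs of sites over 1 kb apart in 532 genes, 73.7% went the same way, against a permuted mean of 57.3% (p 0.0001, the smallest that 10000 permutations can give), and 81.2% did so without floor folds, against 61.6%. This may reflect signal that follows transcript amount or a methylation change common to the whole transcript, and these readings cannot be separated here because input values were not analysed.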
